A study of Mus musculus with 2 samples.

How the data were processed

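Chromatin accessibility was measured by DNase-seq in urinary bladder from female adult B6CASTF1/J mice, a first-generation cross of C57BL/6 and CAST mice, aged 18 to 20 months per the labels. DNase I cuts DNA where it is not covered by nucleosomes, so that regions dense in cuts mark accessible chromatin. The series holds 2 libraries of 1 group, which the labels give as biological replicates 1 and 2, from separate tissue samples listed under 1 strain donor record. Nothing in the labels says whether the samples came from 1 animal or more, so the spread between the libraries may include technical spread.

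Peak lists, footprints and stretches of significant cut rate, all deposited, were used per library, all on the mm10 build per the deposited file listing and none pooled over libraries. The aligner, the caller and their versions are not given in the sources used here. Each library has a longer and a shorter deposited peak list. Every peak of the longer list held a base with a cut-rate false discovery rate, a value on the p-value scale that the authors deposited per stretch, under 0.05, and every peak of the shorter list held a base under 0.001. The deposited peak signal is a whole multiple of 1 step per library within a tolerance of 0.02, for 100% of the peaks, so it is a count scaled by 1 factor per library. The factor's meaning is not stated. The steps were 0.00853 in replicate 1 and 0.00884 in replicate 2, which gives replicate 1 a total 1.04 times that of replicate 2 if both libraries were scaled to the same total. In these steps the median peak held 96 counts in replicate 1 and 86 in replicate 2, and the total depth is unknown. The deposited footprint lists carry the same value on the p-value scale, 0.01, in every row, so footprints could not be ranked. No other column was used.

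The longer list was the main list. Positions and sequence came from GRCm38.p6, the same assembly as mm10, and from the GENCODE M21 annotation with 21853 protein-coding genes and 54361 transcription start sites (TSSs). Chromosomes 1 to 19, X and Y were kept. Peaks were shared when they overlapped by at least 1 bp, and signal was compared in 1 to 1 pairs with the largest mutual overlap. Chance overlap came from 20 random placements of the peaks on their own chromosomes, or of footprints inside the library's own peaks. A promoter peak lay within 1 kb of any TSS of a protein-coding gene. A locus was the gene body with 10 kb on either side. Locus peak density left out promoter peaks.

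Before the data were examined, 22 gene lists with 346 genes and 34 consensus motifs were fixed. Whether each gene is particular to the cell type of its list was not tested. For each list the share of genes with a promoter peak, the median locus peak density and the median log2 ratio of summed locus signal were set against 10000 random lists of the same size. For the ratio, the random lists were matched on signal and the values were centred on the median of all loci with a peak in both libraries. Percentiles describe these libraries and are not p-values, since genes are not replicates, and with 1 library on each side no p-value was computed between replicates. A motif ratio is the number of consensus matches on both strands per kb of footprint, with 5 bp added on each side, divided by that per kb of peak sequence outside footprints. It is given beside 20 shuffles of the consensus letters. To ask whether lists of the wall other than urothelium moved alike, the spread of their mean ranks was set against 10000 shuffles of their genes among the lists.

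Named genes followed a rule fixed in the same way. For lists of the organ's own cell types and of immune cells these were the 4 genes with the highest mean promoter signal and up to 6 genes with no promoter peak in either library. For other lists the top 2 were taken. The 10 genes with the highest summed locus signal, the 10 strongest shared peaks, the 5 shared peaks that differed most in each direction, and the motifs with the 8 highest and 4 lowest ratios completed the rule. Some genes that the rule takes are not reported here. Other genes and motifs named were chosen after their values were seen: Actg2, Lmod1, Myocd, Chrm2, Pgm5, Krt18, Junb and Fos, and GRHL, AP-1 and the 4 motifs drawn by quintile of the ratio.

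Values are means and SD over n = 2 libraries. Alternatives covered promoter and locus width, the overlap that counted as shared, the 42295 strongest peaks of each library and the shorter list. Others were matching on promoter CpG or gene length, other scalings, footprint edges, the motif background, and each library on its own. The 42295 peaks are 50% of the longer list of replicate 1 and a smaller part of that of replicate 2. Of the 10 alternatives for the difference between replicates by list, 6 were added after seeing the data, as was the whole comparison of motifs between replicates with its alternatives. The measures compared over alternatives were also chosen after values had been seen: the number of lists in the outer 2.5% on either side, the number of motifs above every shuffle in both libraries, the X to autosome ratio, the promoter share and the Pearson correlation. The functions were tested on simulated data: of 100 lists of 25 loci with a planted log2 difference of 0.5, 100 passed the outer 2.5% of random lists, as did 4 of 100 unchanged lists, and of 100 unchanged promoter lists 9 did, above the nominal 5. The log2 ratios were shuffled over the loci before planting. Differences under 0.5 and lists of other sizes were not simulated, so these tests do not tell how often smaller differences would be found. A planted motif ratio of 6 came back as 5.89. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads of the 2 parental genomes were not told apart here. How well reads from the CAST genome aligned to the reference, and whether this changed peak signal or peak numbers, cannot be tested from peaks and footprints. Reads, alignments and signal tracks were not analysed here.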

Results

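Accessible chromatin was mapped by DNase-seq in urinary bladder of aged female mice of the B6CASTF1/J cross, in 2 libraries given as biological replicates 1 and 2. The bladder wall holds an epithelium, the urothelium, on connective tissue and smooth muscle. The longer deposited lists held 84591 peaks in replicate 1 and 112174 in replicate 2, a ratio of 1.33, and covered 16.4 Mb and 21.6 Mb. The mean was 98383 ± 19504 peaks (SD, n = 2). Median peak signal was 0.819 and 0.760, and median peak width was 199 bp and 188 bp. The design holds no second group, so the comparisons are between the replicates and between gene groups within each library.

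The first comparison asked how far the accessible regions of replicate 1 returned in replicate 2. Of the peaks of replicate 1, 84.7% overlapped a peak of replicate 2, and of those of replicate 2, 64.1% overlapped one of replicate 1. Randomly placed peaks overlapped at 1.74% and 1.32%. The strongest quintile of peaks returned almost whole, at 99.6% and 99.0%, while the weakest returned at 57.5% for replicate 1 and 21.1% for replicate 2. Of the peaks called in 1 library only, 12980 were in replicate 1 and 40318 in replicate 2, and 1088 and 5653 of these lay above their own library's median signal. At equal numbers of strong peaks, 42295 per library, the shares were 82.3% and 82.4%.

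**Figure D1:**
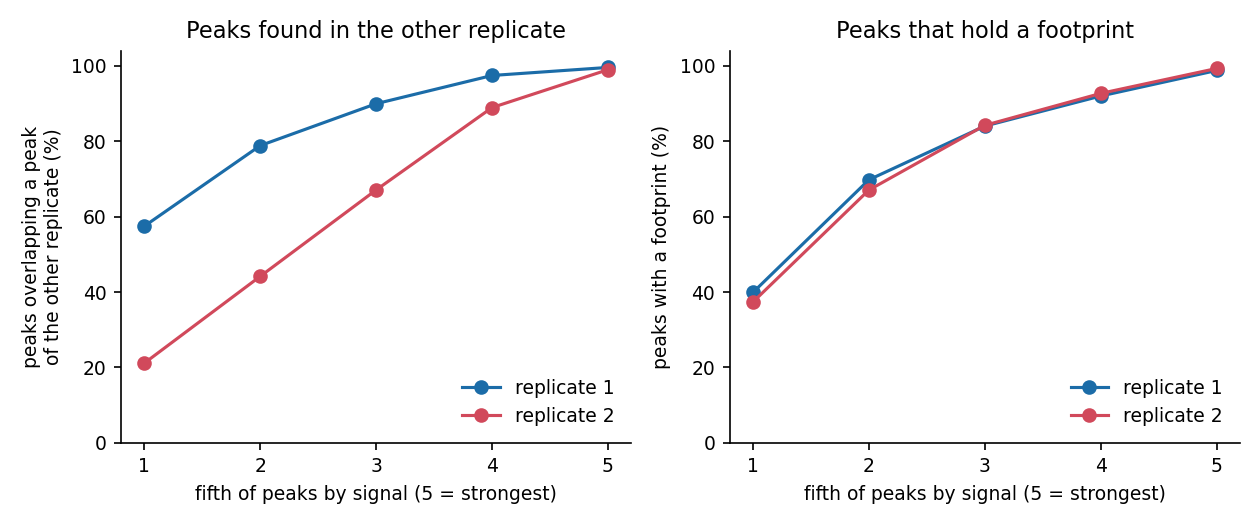
Left, share of peaks (%) that overlap a peak of the other replicate, and right, share of peaks (%) that hold a footprint, by quintile of peak signal within each library (5 is the strongest); points are single libraries. Overlap reached 99.6% and 99.0% in the strongest quintile and differed most in the weakest, at 57.5% for replicate 1 and 21.1% for replicate 2.

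Log2 signal of the 70427 paired peaks had a Pearson correlation of 0.907 and a Spearman correlation of 0.874 across peaks, which are not independent replicates. The median log2 ratio of replicate 2 over replicate 1 was 0.14, and its SD after centring was 0.50, a factor of 1.41. After centring, 77.5% of pairs lay within 1.5-fold and 94.7% within 2-fold. When pairs were split into 3 groups by mean signal, this spread was 1.84 times that of the counts alone among the weakest and 3.72 times among the strongest. The part beyond counts holds any difference between the tissue samples as well as technical spread.

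Promoters were the most enriched class of peak positions. Of all peaks, 27.0% ± 2.85 (SD, n = 2) lay within 1 kb of a TSS, against 2.62% of randomly placed peaks. Introns held 32.8% ± 1.54 against 37.0% at random, exons 3.18% ± 0.0464 against 2.52%, and sequence between genes 37.0% ± 1.36 against 57.9%. Promoter peaks were also stronger, with a median signal of 1.48 and 1.27 in the replicates against 0.708 and 0.663 between genes. A promoter peak was found at 14011 protein-coding genes in replicate 1 and 14509 in replicate 2, with 13771 in both and 7104 of 21853 genes without one in either.

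Urothelium genes were open at nearly all promoters in both libraries. All 25 had a promoter peak in replicate 1 and 24 in replicate 2, and the mean share of 98.0% ± 2.83 stood at the 99.99th percentile of random lists. Klf5, an epithelial transcription factor gene at chromosome 14, 99298691 to 99315036, led the list with a promoter signal of 7.20 ± 0.518 (SD, n = 2). Gata3, a transcription factor gene of the urothelium, followed at 5.54 ± 0.327, then Upk2, which encodes a uroplakin of the luminal surface (chromosome 9, 44452715 to 44454976), at 3.65 ± 0.393, and Cldn4, a tight junction gene, at 3.63 ± 0.154. Away from promoters, urothelium loci held a median of 0.883 ± 0.136 peaks per 10 kb, against a random median of 0.290, and stood at the 100th percentile in both libraries.

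Fibroblast genes had promoter peaks at 21 and 20 of 22 genes, the 99.7th percentile. Among the 42295 strongest peaks of each library, 18 and 15 had one, the 93.1th percentile, inside the range of random lists. Col1a1, a chain of type I collagen, had a promoter signal of 3.90 ± 0.890, Gas1 3.40 ± 1.09, Gli1, a transcription factor of the hedgehog pathway, 3.29 ± 1.08, and Pdgfra, a growth factor receptor of fibroblasts, 2.58 ± 0.163. Mfap5 had none in either library. The fibroblast locus peak density of 0.666 ± 0.0454 per 10 kb was at the 99.7th percentile, and at the 97.4th, just inside the range, when loci took in 50 kb on either side.

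Smooth muscle genes were split between the replicates at promoters. In replicate 1, 22 of 24 had a promoter peak, the 99.9th percentile, and in replicate 2 only 17 did, the 66.7th. Among the 42295 strongest peaks of each library, 13 did in each, the 41.1th percentile of the mean. The 5 genes that had one in replicate 1 alone were Actg2, Lmod1, Myocd, Chrm2 and Pgm5, each with a signal of at most 0.759 there, below that library's median peak. Some strong promoters were nearly equal in both: Tpm1, a tropomyosin gene at chromosome 9, 67022590 to 67049406, had 8.98 ± 0.0239 and Smtn, the smoothelin gene, 5.40 ± 0.0480. Synm had 5.42 ± 0.499. Kcnmb1 and P2rx1, a channel subunit and an ATP receptor of smooth muscle, had no promoter peak in either library, although the P2rx1 locus held 7 and 8 peaks. Smooth muscle loci held 0.549 ± 0.169 peaks per 10 kb, the 98.6th percentile. Lymphoid tissue (0.590 in each library), myeloid (0.483 ± 0.140) and pericyte loci (0.511 ± 0.155) followed at the 95.4th, 91.5th and 90.4th percentiles, and apart from immediate early genes the other lists lay between the 7.04th (pancreatic acinar) and the 85.3th (glia and peripheral neuron). Lymphoid tissue loci were above the range in replicate 1 alone, at the 98.9th. With 50 kb on either side T cell loci rose from the 48.3th to the 97.7th percentile and pancreatic acinar loci from the 7.04th to the 95.2th, while glia and peripheral neuron loci fell to the 24.1th.

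Lists of vessels, outer wall and nerves lay inside the range of random lists when all peaks were used. Endothelium genes had a promoter peak at 10 of 19 genes in each library, the 13.4th percentile. Esam had the highest promoter signal, 2.35 ± 0.168, followed by Prox1, 1.04 ± 0.176, Eng, 0.959 ± 0.0303, and Kdr, 0.938 ± 0.0359. Pecam1, Emcn, Vwf, Cldn5, Sox17 and Sox18 had none, yet the Pecam1 locus held 15 and 17 peaks and that of Vwf 9 in each. Pericyte genes reached 7 and 8 of 10 (the 72.1th percentile), led by Kcnj8 at 1.56 ± 0.206, Foxs1 at 1.28 ± 0.358, Mcam at 1.25 ± 0.314 and Pdgfrb at 1.11 ± 0.139, with none at Higd1b and Cox4i2. Mesothelium genes, of the cells that cover the outer wall, reached 4 of 8 in each library (the 19.8th percentile), with Krt8 at 2.10 ± 0.573, Wt1 at 1.35 ± 0.0156, Bnc1 at 0.812 ± 0.0266 and Rspo1 at 0.559 ± 0.0657, and none at Msln, Lrrn4, Gpm6a and Muc16. Glia and peripheral neuron genes had 5 and 7 of 12 (the 17.1th percentile). Among them, Ret had 0.753 ± 0.160, S100b 0.689 ± 0.0624 and Prph 0.599 ± 0.00283. Sox10, Foxd3 and Th had none. Among the 42295 strongest peaks of each library, endothelium had 5 and 1 of 19 genes, and glia and peripheral neurons 1 of 12 in each library. Both lists fell below the range there, to the 0.208th and 0.03th percentiles.

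**Figure D2:**
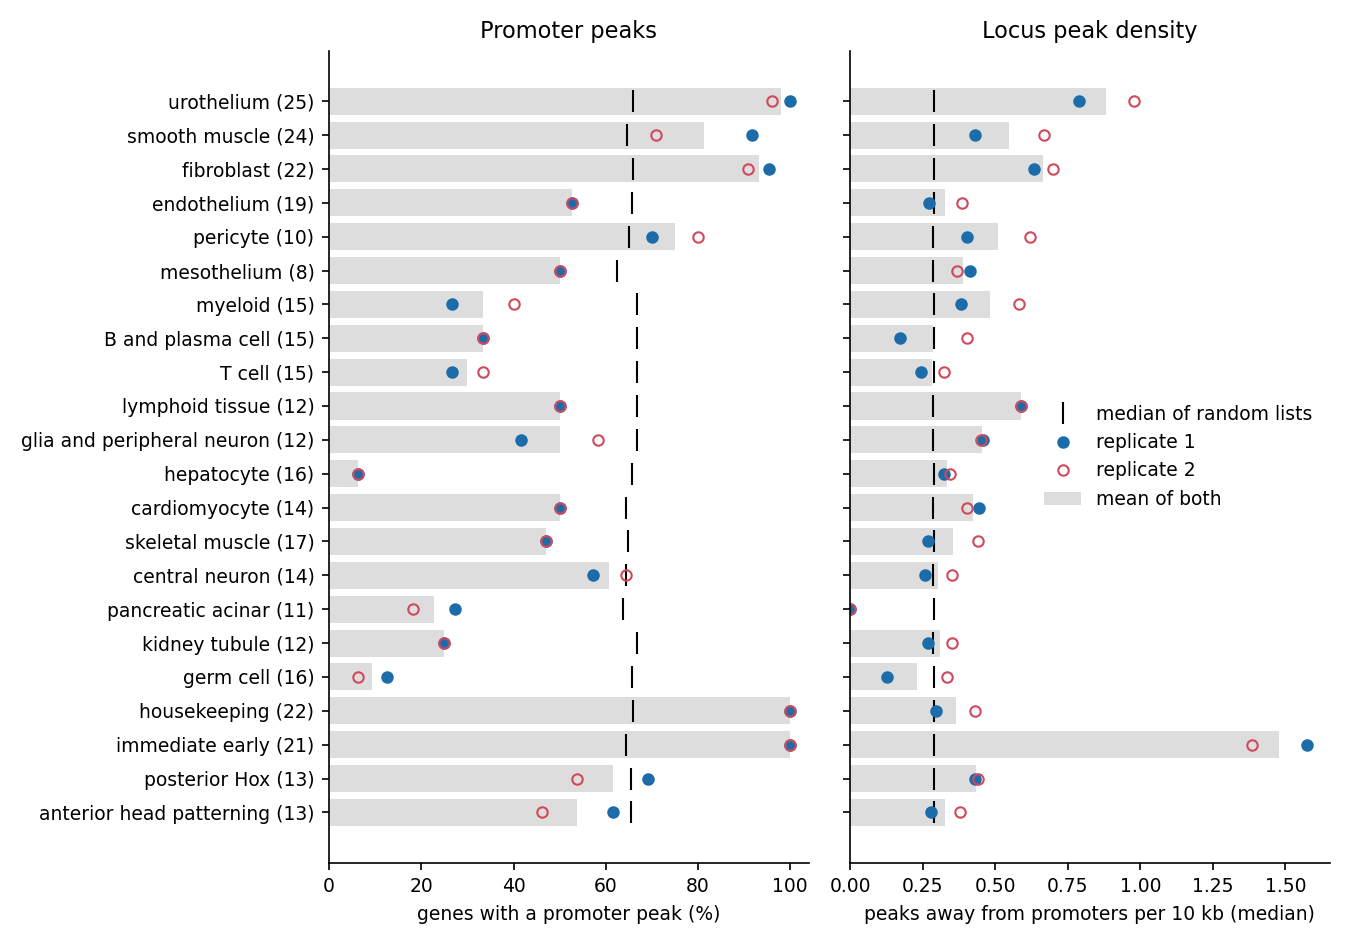
Left, share of each gene list (%) with a promoter peak, and right, median number of peaks away from promoters per 10 kb of locus, for 22 lists with the number of genes in brackets. Points are the 2 libraries, bars their means and black ticks the median of 10000 random lists; urothelium stood at 98.0% and 0.883 peaks per 10 kb against random medians of 66.0% and 0.290.

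Immune lists had few promoter peaks. Myeloid genes had them at 4 and 6 of 15 (the 1.08th percentile), B and plasma cell genes at 5 of 15 in each library (the 0.765th), T cell genes at 4 and 5 of 15 (the 0.368th) and lymphoid tissue genes at 6 of 12 in each (the 14.6th). With random lists matched on promoter CpG content the first 3 moved to the 31.1th, 32.3th and 7.05th percentiles, inside the range of random lists. A few promoters stood out. Irf8, a transcription factor gene of macrophages, had 3.04 ± 0.0398, and Cd68 had 1.11 ± 0.0640, while Spi1 had a peak of 0.999 in replicate 2 only. Ebf1 and Pax5, of the B lineage, had 3.33 ± 0.458 and 1.74 ± 0.338, Cd79b 0.827 ± 0.157 and Bank1 0.796 ± 0.149. Tcf7 had 1.02 ± 0.165, Bcl11b 0.652 ± 0.0533, Cd28 0.513 ± 0.0866 and Cd3d 0.369 ± 0.0277. Ltbr had 3.47 ± 0.575, Cxcl12 1.08 ± 0.211, Tnfsf13b 0.842 ± 0.334 and Cxcr5 0.696 ± 0.116.

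No promoter peak was found in either library at 8 myeloid genes, among them Adgre1, Csf1r, Cx3cr1, Mrc1, C1qa and Itgam. The same held for 10 B and plasma cell genes, among them Cd79a, Ms4a1, Blk, Cd22 and Pou2af1, for 10 T cell genes, among them Cd3g, Cd2, Cd4, Cd8a, Lck and Themis, and for the lymphoid tissue genes Ccl19, Ccl21a, Ccr7, Lta and Ltb. Several of these had peaks elsewhere in the locus, 23 and 25 of them at Cx3cr1. The locus windows also cover neighbouring genes.

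Hepatocyte and germ cell genes had the fewest promoter peaks of the 22 lists. Hepatocyte genes had a promoter peak at 1 of 16 genes, Asgr1 (1.86 ± 1.07), and germ cell genes at 2 and 1 of 16, at mean percentiles of 0 and 0.0025. Pancreatic acinar genes had 3 and 2 of 11 and kidney tubule genes 3 in each library of 12, at the 0.508th and 0.368th percentiles. Matching on CpG moved the last 2 to the 10.1th and 14.4th. Cardiomyocyte (7 of 14), skeletal muscle (8 of 17) and central neuron genes (8 and 9 of 14) lay at the 12.5th, 6.67th and 35.8th percentiles, inside the range of random lists. Cardiomyocyte (1 of 14 in each library) and central neuron genes (3 and 4 of 14) fell below it among the 42295 strongest peaks of each library. They lay at the 0.01th and 1.30th percentiles there. Skeletal muscle genes fell below the range within 500 bp of a TSS, at the 0.802th. Some promoter peaks lay within 1 kb of a TSS of another gene too. Without these, 5 and 6 of 14 cardiomyocyte genes, 5 and 6 of 17 skeletal muscle genes, 6 and 7 of 10 pericyte genes, 4 and 6 of 12 glia and peripheral neuron genes and 17 of 22 housekeeping genes had a promoter peak, and the counts of the other lists did not change. The peaks of Myl4 (9.89 ± 1.92), Actn3 (5.82 ± 1.34) and Mylpf (4.09 ± 0.345) also lay within 1 kb of a TSS of Cdc27, Zdhhc24 and Tbc1d10b. Snap25 had 2.02 ± 0.511, Nppb 0.592 ± 0.162, Dazl 3.71 ± 0.578, Rbpjl 1.63 ± 0.317, Bhlha15 0.823 ± 0.199 and Slc34a1 0.773 ± 0.318. Sycp3 had a peak of 0.409 in replicate 1 only.

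Housekeeping and immediate early genes, the latter switched on within minutes of a stimulus, had promoter peaks at every member, 22 and 21, peaks shared with another gene included. Rplp0 and Actb led the housekeeping genes at 11.6 ± 2.26 and 9.67 ± 0.0169, and Jun and Klf6 the immediate early genes at 10.7 ± 0.822 and 9.60 ± 2.54. Immediate early loci had the highest peak density of the 22 lists, 1.48 ± 0.134 per 10 kb. Posterior Hox genes, which pattern the tail end of the body, had promoter peaks at 9 and 7 of 13, led by Hoxa10 (4.85 ± 0.0179) and Hoxc10 (3.17 ± 0.559). Anterior head patterning genes had 8 and 6 of 13, led by Barhl1 (1.83 ± 0.255) and Lhx2 (1.36 ± 0.193). Both lists were inside the range of random lists, at the 40.5th and 24.5th percentiles, and under it with CpG matching, at the 0.685th and 0.130th. Immediate early genes lay at the 95.3th percentile with that matching.

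The highest summed locus signal was that of Gm20388, a gene model whose span also holds Gse1. Gm20388 (chromosome 8, 119910841 to 124345722) had 795 ± 81.9 and Fgfr2, annotated from 130162451 to 133123350 on chromosome 7, had 270 ± 44.0. Mid1 (216 ± 39.9) and Gm21887 (102 ± 13.9) lie at the end of the X chromosome. Gse1 had 103 ± 5.18, Camta1 92.1 ± 22.0, Gm37240 79.0 ± 6.93, Sfi1 78.4 ± 11.6, Midn 69.9 ± 4.82 and Samd4b 69.0 ± 6.20. Among shared peaks, the strongest lay outside protein-coding genes at chromosome 17, 39846781 to 39846920, with a signal of 49.95 ± 17.9. Of the 10 strongest, 3 were introns of Mid1 or Gm21887 between 169997921 and 170010160 on chromosome X, with means of 39.5 ± 10.5, 31.6 ± 7.83 and 27.7 ± 6.57. Others lay in untranslated exons of Cers5 (36.5 ± 3.57) and Lars2 (29.5 ± 7.58), in an intron of Kpna1 (28.5 ± 13.7), and nearest to Igf2bp3 (30.8 ± 15.7), Pak3 (30.7 ± 10.3) and Hjurp (28.2 ± 3.08). No regions of these chromosomes were left out here for repeated sequence. Whether reads from repeat copies raised the highest signals was not tested, so these need not be the most accessible sites.

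Compared between replicates, urothelium, fibroblast and immediate early loci were lower in replicate 2 than other loci of like signal. The median centred log2 ratio was -0.18 for urothelium (the 0.745th percentile, 20 of 25 genes lower), -0.19 for fibroblasts (0.460th, 13 of 22 lower) and -0.26 for immediate early genes (0.160th, 20 of 21 lower). Higher and lower here are relative to the median of all loci and not to the raw signal. Gata3 counted as lower, at -0.15, although its summed locus signal was 11.7 in replicate 1 and 12.8 in replicate 2. Junb, at -0.37, Fos, at -0.47, Krt18, at -0.60, and Cldn4, at -0.47, were among the lower genes. Skeletal muscle genes, with 7 higher and 6 lower, had a median of 0.44 (98.9th), which turned to -0.059 with promoter peaks only. Some of these lists moved inside the range of random lists under other settings. Fibroblast genes did with paired peaks only (-0.09, the 5.98th percentile) and with the number of peaks (-0.28, the 3.64th). Immediate early genes did with promoter peaks only (-0.07, the 23.7th), and urothelium with quantile normalization (-0.14, the 3.755th) and without peaks that hold a CTCF motif (-0.16, the 2.64th). Myeloid (0.27, 6 higher and 6 lower), T cell (0.29, 7 higher and 4 lower) and central neuron genes (0.28, 10 higher and 2 lower) stood at the 96.0th, 96.2th and 95.4th percentiles, B and plasma cell genes (0.26, 10 of 12 higher), endothelium (0.20, 13 of 16 higher) and lymphoid tissue (0.30, 7 of 10 higher) between the 89.4th and 92.1th, and smooth muscle (0.01) at the 62.2th. Without promoter peaks the medians turned to -0.14 for myeloid, -0.17 for lymphoid tissue, -0.09 for endothelium and -0.03 for T cell genes. Mesothelium (-0.27) lay at the 2.51th and pericyte genes (0.31) at the 91.4th, and the other 9 lists between the 7.13th (germ cell) and the 81.2th (pancreatic acinar). The pericyte median turned to -0.05 with quantile normalization and to -0.012 with the 42295 strongest peaks of each library. It was -0.0024 with paired peaks only and -0.0032 without peaks that hold a CTCF motif. In paired peaks corrected for GC content, width and strength it was -0.11 (the 7.105th percentile). With 1 library on each side these values describe the 2 libraries, and the number of peaks in place of signal left urothelium at the 49.4th percentile.

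**Figure D3:**
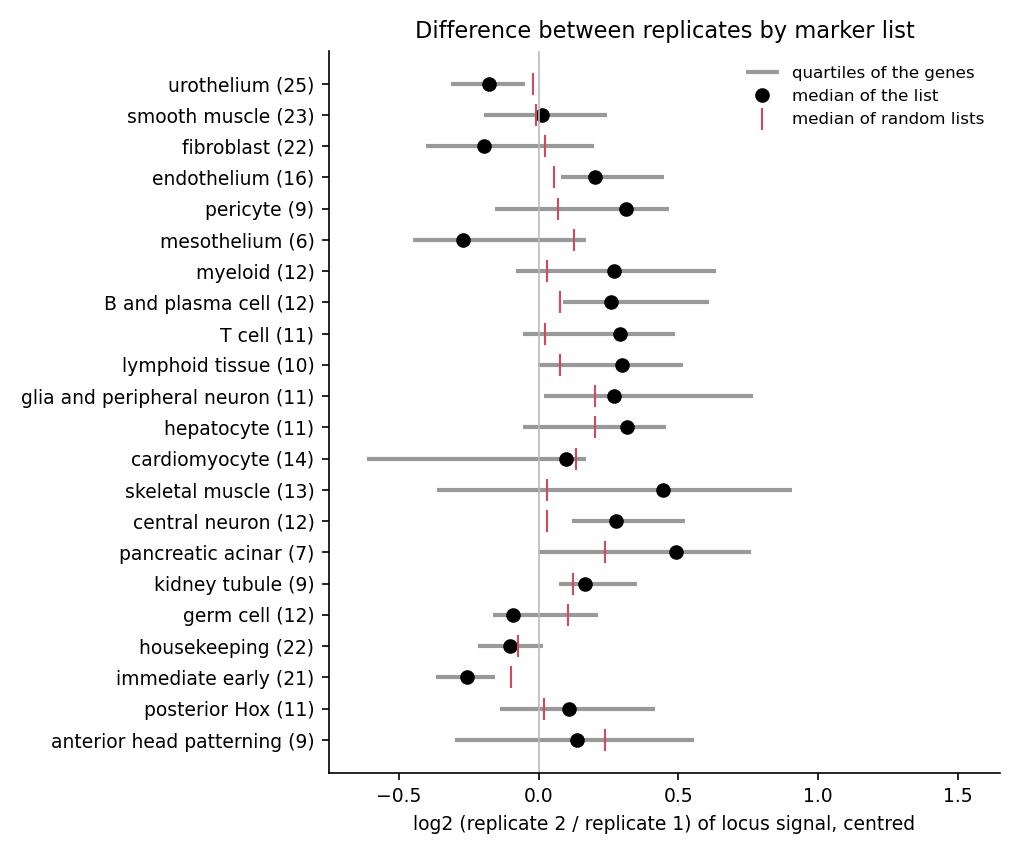
Median centred log2 ratio of summed locus signal, replicate 2 over replicate 1, for 22 gene lists with the number of genes that had a peak in both libraries in brackets. Black points are list medians, grey lines the quartiles of the genes and red ticks the median of random lists matched on signal; urothelium lay at -0.18 and immediate early genes at -0.26.

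Single shared peaks differed more widely toward replicate 2. The 5 peaks with the largest ratio, all higher in replicate 2 before centring by 5.04 to 6.16 times, lay near Mocs1 (chromosome 17, 49400221 to 49400380; 0.452 and 2.78), in introns of Rps6ka3 and Pogz, near Hrh4, and near Gm11168 in sequence that is 100% repeat masked. The 5 with the smallest ratio were lower by 2.29 to 2.99 times and lay near Aldh1b1 (chromosome 4, 45755961 to 45756200; 1.64 and 0.548), near Gm21860 on the Y chromosome, in an intron of Rbfox3, near Tagap, and in an untranslated exon of Smim19. In a comparison of all 34 motifs added after seeing the data, CTCF had the largest difference and was singled out for that. Paired peaks with a CTCF motif had a median log2 ratio 0.69 above that of other paired peaks, a factor of 1.61, and 95.2% of these 5801 peaks were higher in replicate 2 against 60.0% of the rest. After matching on GC content, width and strength of the peaks the difference was 0.37, a factor of 1.29. CTCF is a zinc finger protein that holds chromatin loops and domain borders. The motif was in 0.795% of the quintile of peaks lowest in replicate 2 and in 27.9% of the highest. The motif of AP-1, the dimer of Fos and Jun proteins, went the other way, from 19.5% to 6.37%. AP-1 was not alone in this: KLF fell from 28.6% to 9.11% and SP from 7.90% to 1.69%, while NFI went from 1.80% to 2.12%. Only CTCF was matched on GC content, width and strength.

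**Figure D4:**
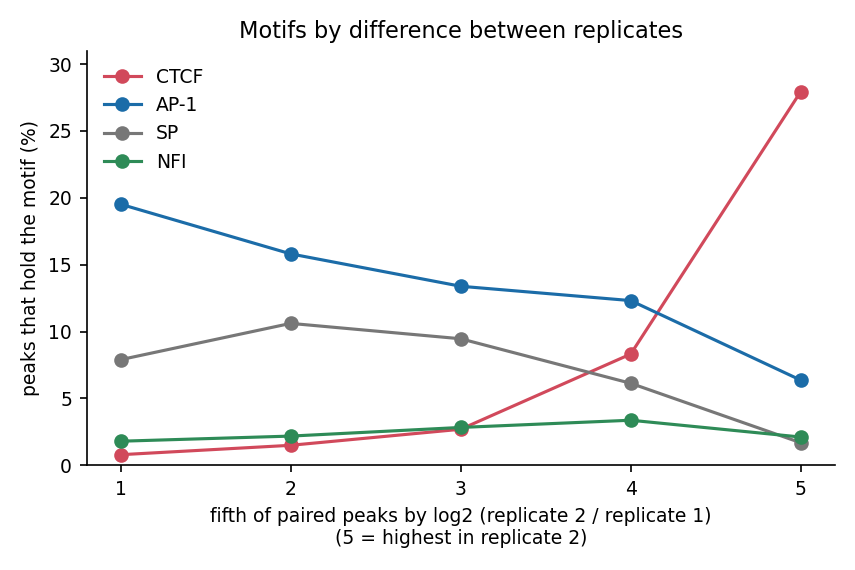
Share of paired peaks (%) that hold the consensus of CTCF, AP-1, SP or NFI, by quintile of the log2 ratio of replicate 2 over replicate 1 (5 is highest in replicate 2). The CTCF share rose from 0.795% to 27.9% and the AP-1 share fell from 19.5% to 6.37%.

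Footprints are short stretches inside accessible DNA that were cut less, as under a bound protein. There were 176795 in replicate 1 and 229390 in replicate 2, a ratio of 1.30, with median widths of 9 bp and 10 bp, and 92.0% and 92.1% overlapped a peak of their library. A footprint lay in 76.5% ± 0.542 of peaks, from 39.9% and 37.4% in the weakest quintile to 98.8% and 99.3% in the strongest. Footprints returned less often than peaks: 55.1% of those in replicate 1 overlapped one in replicate 2 and 40.7% the other way. Footprints are far shorter than peaks, which by itself lowers overlap. Among footprints in peaks the shares were 54.0% and 39.8%, against 22.8% and 15.4% when these were placed at random inside peaks. The random places did not follow peak strength, so they may understate chance overlap.

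NRF1 had the highest density in footprints relative to the rest of the peaks. NRF1, a regulator of genes for mitochondrial function, was 32.9 ± 1.60 times as dense there, CTCF 16.8 ± 5.55 times and CREB 12.9 ± 0.933 times. RFX (9.32 ± 1.29), REST (8.60 ± 3.01), SP (7.27 ± 0.478), NFI (6.82 ± 0.243) and KLF (3.89 ± 0.101) followed. RFX rested on 31 and 33 matches in footprints, and REST on 79 and 173. Of the 34 motifs, 11 exceeded all 20 shuffles of their letters in both libraries, and among the 8 named, REST did not. Footprints were richer in GC than peak sequence outside them, at 61.4% against 55.5% in replicate 1 and 59.0% against 53.4% in replicate 2. The shuffles keep the letters of a motif but not their order, so they do not account for CpG content. With sequence outside peaks as the background, REST was the highest at 269 ± 90.3, over every shuffle but with 4 matches in that background, followed by CTCF (110 ± 10.2), YY1 (71.2 ± 7.39) and NRF1 (65.5 ± 12.97). The lowest ratios were those of PU.1 (0.731 ± 0.0328), GATA (0.721 ± 0.00513), steroid receptors (0.649 ± 0.0615) and FOX (0.534 ± 0.0181), all with shuffled medians also below 1. The motifs of GRHL, an epithelial factor (1.18 ± 0.0304), and AP-1 (1.28 ± 0.0131) did not exceed every shuffle, but AP-1 was 3.83 ± 0.167 times as dense in peaks as in sequence 200 to 400 bp outside them, with a shuffled median of 0.812, a ratio added after seeing the data.

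**Figure D5:**
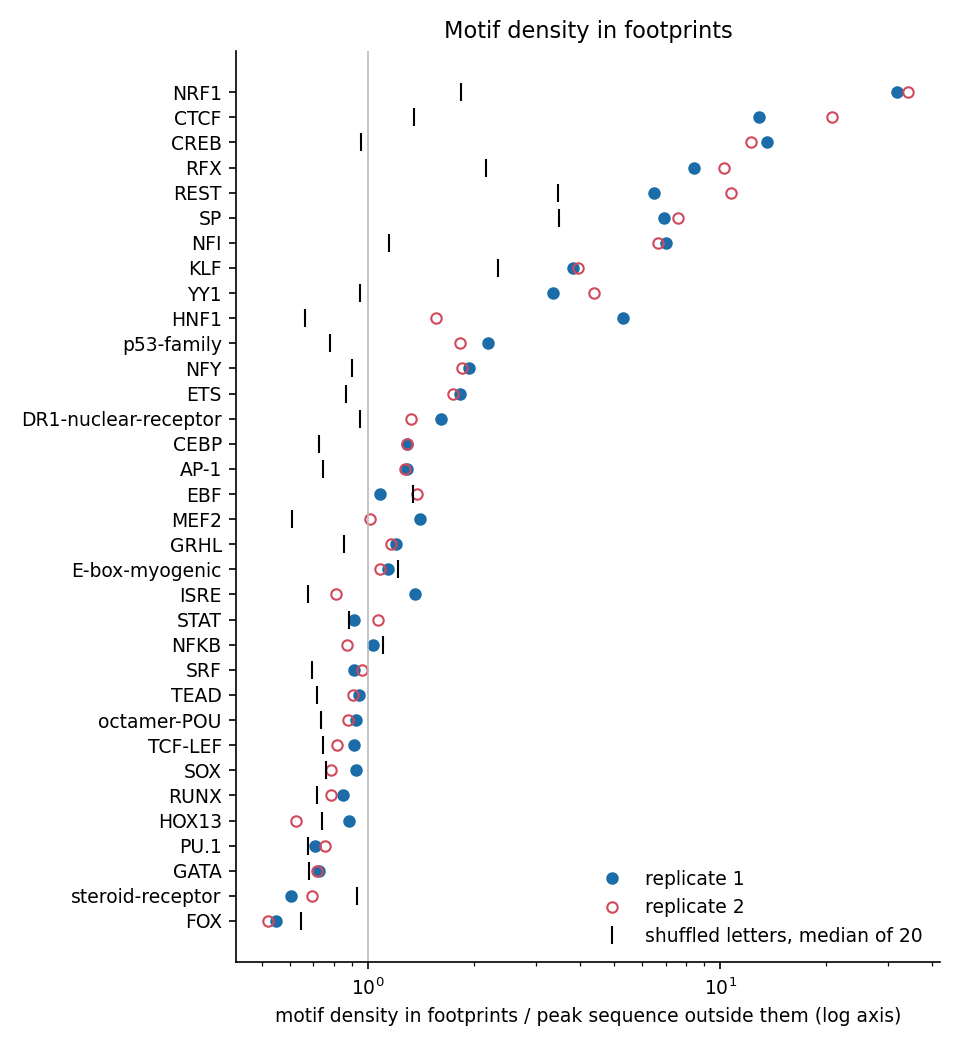
Density of 34 consensus motifs in footprints divided by that in peak sequence outside footprints, on a log axis, with points for the 2 libraries and black ticks for the median of 20 shuffles of the consensus letters. NRF1 stood highest at 32.9 and FOX lowest at 0.534.

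The X chromosome was sparse in peaks. It held 12.7 and 17.7 peaks per Mb, 0.359 and 0.378 of the autosome median of 35.4 and 46.9, and no autosome fell below 26.9 and 36.2. Per protein-coding gene the X held 2.19 and 3.06 peaks against 4.21 and 5.60. Peaks on the X were weaker too, with a median signal of 0.571 and 0.530 against 0.827 and 0.769 on autosomes. The densest autosome was chromosome 11 at 59.4 ± 11.1 peaks per Mb. The Y chromosome, absent from female tissue, had 41 and 37 peaks. Of these, 19 and 24 lay beyond 90.7 Mb at its distal end, a limit set to hold the stretch shared with the X. The other 22 and 13 lay before it.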

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

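The motif difference between replicates and 6 alternatives of the difference by list were chosen after the result was seen. The share of peaks of replicate 1 found in replicate 2 was 84.7%, and 71.4% with 50% reciprocal overlap, 82.3% at equal numbers of strong peaks and 88.1% in the shorter lists. The other way it was 64.1%, and 53.9%, 82.4% and 65.1%; the 2 directions differ with the lengths of the lists. Locus peak density put 4 or 5 of 22 lists in the outer 2.5% of random lists under every setting, but not always the 4 reported: with 50 kb on either side fibroblasts left, at the 97.4th percentile, and T cells entered, at the 97.7th, and without replicate 2 lymphoid tissue entered. Of its values by list, 35 moved by more than the spread of the replicates or crossed the limits of random lists, and 75 did neither. Single libraries and matching on gene length cannot move a value beyond that spread, so there only a crossing could count. The Pearson correlation of log2 signal was 0.861 in the stronger 50% of pairs and 0.902 in the shorter list. The promoter share of peaks was 21.2% with 500 bp, 33.0% with 2500 bp, 30.6% of shared peaks, 39.3% of the stronger peaks, and 25.03% to 29.1% in single libraries; a wider window holds more peaks by construction. The X to autosome ratio was 0.252 among stronger peaks, 0.339 in the shorter list and 0.359 to 0.378 in single libraries. With 50% reciprocal overlap 33.6% of footprints were shared.

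At promoters 11 lists were apart from random lists. Matching on promoter CpG gave 7, with posterior Hox and anterior head patterning entering, and single libraries gave 11 to 12. The 42295 strongest peaks of each library gave 15. There endothelium, glia and peripheral neurons, cardiomyocytes, central neurons and anterior head patterning entered, and fibroblasts left, at the 93.1th percentile. With 2500 bp myeloid genes left (the 4.575th), and with 500 bp skeletal muscle entered. For the difference between replicates, 4 lists were apart; 2 were with quantile normalization and 1 with the number of peaks. With 50 kb on either side 6 were: posterior Hox (100th), hepatocyte (99.9th) and anterior head patterning genes (99.3th) entered, and skeletal muscle left. Among alternatives added after seeing the data, 2 were with promoter peaks only, 2 with paired peaks only, and 6 with the 42295 strongest peaks of each library. In the last, lymphoid tissue, glia and peripheral neurons, and central neurons entered and skeletal muscle left. The skeletal muscle median turned to -0.059 with promoter peaks only and to -0.019 with paired peaks corrected for GC content, width and strength. Urothelium lay at the 49.4th percentile with the number of peaks and at or under the 3.755th in the other settings. Between 10 and 16 motifs exceeded all shuffles, and 13 in each single library. Of the alternatives for promoter signal of named genes, 278 lay within the spread of the replicates and 18 did not. The 278 include the single libraries, which with n = 2 always lie within that spread. Against sequence outside peaks, PU.1 rose to 1.24 and the steroid receptor motif to 1.20. The cause of these changes was not tested. Footprints could not be ranked, so the stricter footprint threshold was not run. Total depth is unknown, and counts limit the weakest peaks most. The CTCF difference, 0.69, was 0.37 after matching.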

Other observations

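Of the tests below, that of the other lists of the wall beside urothelium, that of the counting step and that of CTCF peaks in the surplus were chosen after their result was seen, and the comparison of motifs between replicates was itself added after seeing the data. Beyond CTCF, paired peaks with a REST motif also leaned to replicate 2, with a median log2 ratio 0.48 above other peaks, though they were 0.175% of paired peaks. Peaks with motifs of p53-family proteins, NRF1, KLF and AP-1 had median log2 ratios that differed from other peaks by -0.19, -0.18, -0.17 and -0.16. Their own medians were -0.048, -0.033, 0.028 and 0.0077, so KLF and AP-1 peaks were not lower in replicate 2 before centring. These motifs were not matched on GC content, width or strength. Among peaks called in 1 library only, the CTCF motif was in 5.72% of those of replicate 2 and in 0.431% of those of replicate 1. The ratio also followed the form of the peak: the median log2 ratio was 0.37 in the quintile lowest in GC content and 0.01 in the highest, and 0.35 in the narrowest peaks, with a median of 178 bp, against -0.01 in the widest.

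The higher CTCF peaks in replicate 2 may reflect how the libraries were cut or selected by fragment size, but no value here measures either. Shuffled orders of the consensus letters gave at most 0.022, which argues against base composition of the motif. The difference was at least 0.64 on each of the 20 chromosomes tested, 1 to 19 and X, which argues against a change at a few regions. Matching on GC content, width and strength lowered it from 0.69 to 0.37, so these properties could account for part of it, and what share they cause cannot be told apart from what CTCF sites share by nature. No biological explanation was tested, since the design has 1 group.

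Urothelium signal was lower in replicate 2 relative to the median of all loci, and leaving out the CTCF peaks changed the list median little. The list median was -0.16 without them against -0.18 with them. Without them the list stood at the 2.64th percentile, just inside the range of random lists. Without them, centring took 0.24 off the log2 ratio of every locus. The difference is thus relative and not a lower raw signal. The list median was -0.20 in paired peaks corrected for GC content, width and strength, as in uncorrected pairs. A smaller share of urothelium as the only change would raise the other cell types of the wall alike. Whether they moved alike cannot be told apart from the spread of their genes. Each of these lists would also lie above the middle of random lists. Fibroblast genes (0.460th percentile) and mesothelium genes (2.51th) did not, while smooth muscle, endothelium and pericyte genes did. The fibroblast value argues against the explanation for that list in the main setting. The mesothelium value rests on few genes with a peak in both libraries. Among these was Krt8 (-0.48), a keratin gene, and the urothelium list holds keratin genes too. With lists on both sides, the explanation as a whole could not be decided. After centring, fibroblast (-0.19) and mesothelium genes (-0.27) were lower and endothelium (0.20) and pericyte genes (0.31) higher. Smooth muscle was at 0.01 and glia and peripheral neurons at 0.27. The order of these lists changed with the setting: mesothelium was the lowest here, and fibroblasts were with 50 kb on either side. When the 87 genes of 6 such lists were shuffled among them, the lists lay as far apart by rank in 9.21% of 10000 shuffles. That share was under 5% in 3 of 11 settings. A change in several cell types at once stays untested, as does any difference between animals.

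The larger number of peaks in replicate 2 did not go with a deeper library as far as the steps tell: 1 step was worth 1.04 times as much signal in replicate 2, so its total was the smaller if both were scaled alike. CTCF peaks made up 8.72% of the surplus of 27583 peaks, and without them the ratio of peak numbers was still 1.32. A higher share of cuts inside accessible regions is a possible explanation that was not tested, because reads outside peaks were not analysed here.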
